A study of Mus musculus with 12 samples.

How the data were processed

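Gene expression was measured on 12 Affymetrix mouse arrays, 3 for each of 4 groups labelled 16C, 24C, 40C and 41C. Per the labels' protocols, total RNA was extracted with Trizol, messenger RNA was converted to cDNA and amplified with a NuGEN pico kit, and biotin-labelled material was hybridised by the standard Affymetrix procedure. The deposited values are on the log2 scale, and per the submitters' processing notes they were made by RMA (robust multi-array average) in Partek 6.6. RMA subtracts a background estimate, forces all arrays onto one distribution of intensities and summarises the probes of a probe set. The options used in Partek are not given in the sources used here. Values near background are compressed by this procedure, so folds against a group near background understate the change. No scanner intensities were used here, and no array has a depth in the sense of sequencing: 3 arrays per group limit the precision.

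The table held 45101 probe sets. The platform annotation listed 35890 of them, 34958 with 1 gene and 932 with several, and 9211 were not listed and stayed unnamed. Probe sets with several genes named no gene. The gene IDs of 34754 single-gene probe sets were found in a mouse reference table of assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. Each of 18194 genes was represented by its single-gene probe set with the highest mean over the 12 arrays. For 9012 genes other single-gene probe sets existed, and disagreement is stated where a named gene is concerned. Of 14 genes of interest written down beforehand, 10 were measured, and Pten, Akt3, Trp53 and Rbm3 were not analysed here.

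Groups were taken from the condition given in the labels. The replicate numbers follow deposit order and pair no samples. The sample names carry one final tag in 16C and another in 24C, 40C and 41C, so the tag could not be entered as a covariate or block in comparisons with 16C. One linear model with a mean per group was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 8 residual degrees of freedom and a prior of 5.21, and no filter on dim genes. Adjusted p-values in the text are from this fit or from the limma gene list tests, two-sided, with Benjamini-Hochberg adjustment within a comparison. A gene was called at an adjusted p under 0.05 and a log2 difference of at least 1 in size, and a list member is described as having risen or fallen, or as higher or lower, at an adjusted p under 0.05 alone. The 6 comparisons were each of the 3 groups with 16C and the 3 pairs among 24C, 40C and 41C. An exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1, so p-values rest on the spread pooled over genes and groups.

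Gene lists were fixed before the data were examined: 47 lists of pathways, lineages and markers of other cell types, of which 46 were tested in each comparison with camera at a preset correlation of 0.01, Benjamini-Hochberg over the lists. Y-linked genes and Xist were given as values only. Camera asks whether a list shifted more than other genes. Camera with an estimated correlation between members was run as an alternative, as was fry, which tests only the list's own direction. Another 5 lists (skeletal, heart and smooth muscle, fat, and cartilage or bone genes) were written after the leading genes had been seen, and their p-values are unadjusted.

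The genes named in the text follow a rule fixed before the data were examined. For each comparison with 16C, these were the 7 largest rises and 7 largest falls among called genes whose 3 arrays in one group all lay above the 3 in the other, whose higher mean was at or above the table's median of 5.49, and whose symbol was no placeholder. For the other comparisons and for sets of comparisons the rule took 4 and 4. It added the 3 members with the largest change of each list that passed, and the 10 measured genes of interest. Other genes are named as chosen after their values were seen.

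The alternatives changed one choice at a time: a filter on dim genes, the mean of all probe sets of a gene or each probe set on its own, each array shifted to one median, cyclic loess, quantile normalization, a variance trend with robust hyperparameters, array weights, only the compared groups in the fit, no minimum size, an adjusted p under 0.01, a test against a 1.5-fold change, and each array left out. A fit without the 16C arrays was added after seeing the data. For comparisons that share the 16C arrays, 100 simulations of unchanged groups gave the values that shared controls alone produce.

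The scripts were tested on simulated data of 18194 genes with 50 genes changed at each fold size. Of the 2-fold changes, 38% were called in the simulation of 24C versus 16C, 52% for 40C versus 16C, 44% for 41C versus 16C, 42% for 24C versus 40C, 46% for 24C versus 41C and 52% for 40C versus 41C, since 2-fold is the size at which calls begin. In each of the 6 simulations, 100% of the 3-fold and 4-fold changes and 0% of the 1.5-fold changes were called, and 0 unchanged genes were. All 5 shifted lists of 20, moved by 0.3 log2, were found in each, and 1 unshifted list passed in the simulation of 40C versus 41C. The genes were simulated independently of each other, so these simulations say nothing about lists whose members are correlated. Figures were drawn with matplotlib 3.10.9.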

Results

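Transcript levels were compared in 12 samples of mouse cells that the submitters describe as a melanoma cell line of strain C57/BL6, in a series concerned with the PTEN phosphatase and metastasis. The samples fell into 4 groups of 3, labelled 16C, 24C, 40C and 41C, and 16C was the control with which the other groups were compared. What the codes stand for is not given in the sources used here. Nothing in the labels says whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. All values are log2 RMA expression, given as mean ± SD with n = 3 arrays per group.

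The 16C arrays stood apart from all others. Across the 45101 probe sets, which are not independent replicates, arrays of one group correlated at 0.994 to 0.998, arrays of different groups among 24C, 40C and 41C at 0.991 to 0.995, and 16C arrays with any other at 0.913 to 0.920. Over the 18194 genes, the first principal component, with 89.9% of the variance, separated 16C from the 9 other arrays, and the second, with 3.84%, separated 24C, 41C and 40C. The 16C sample names also carry a tag of their own, so in comparisons with 16C the group and the tag cannot be told apart, while comparisons among 24C, 40C and 41C lie within a single tag. Poly-A spike transcripts, which are added to the RNA before labelling, fell by medians of 1.71, 1.47 and 1.52 in 24C, 40C and 41C against 16C, with 24 of 24 probe sets past the test in each. Hybridisation spikes differed by medians of 0.34, 0.56 and 0.49 the other way. In each comparison 18 of 18 of their probe sets were higher than in 16C, though 0 of 18 passed the test. The difference between 3' and 5' probe sets, a measure of RNA integrity, lay between -0.01 and 0.03 for Gapdh and between 0.09 and 0.20 for b-actin in the 4 groups, both near the top of the scale. For the transferrin receptor it lay between 1.14 and 1.31, and for pyruvate carboxylase at 0.86 in 16C and at -0.11, -0.02 and 0.19 in 24C, 40C and 41C. The 3' probe set of pyruvate carboxylase was itself at 8.43 in 16C and at 6.35, 6.35 and 6.63 in 24C, 40C and 41C. Its difference therefore does not measure RNA integrity alone.

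**Figure D1:**
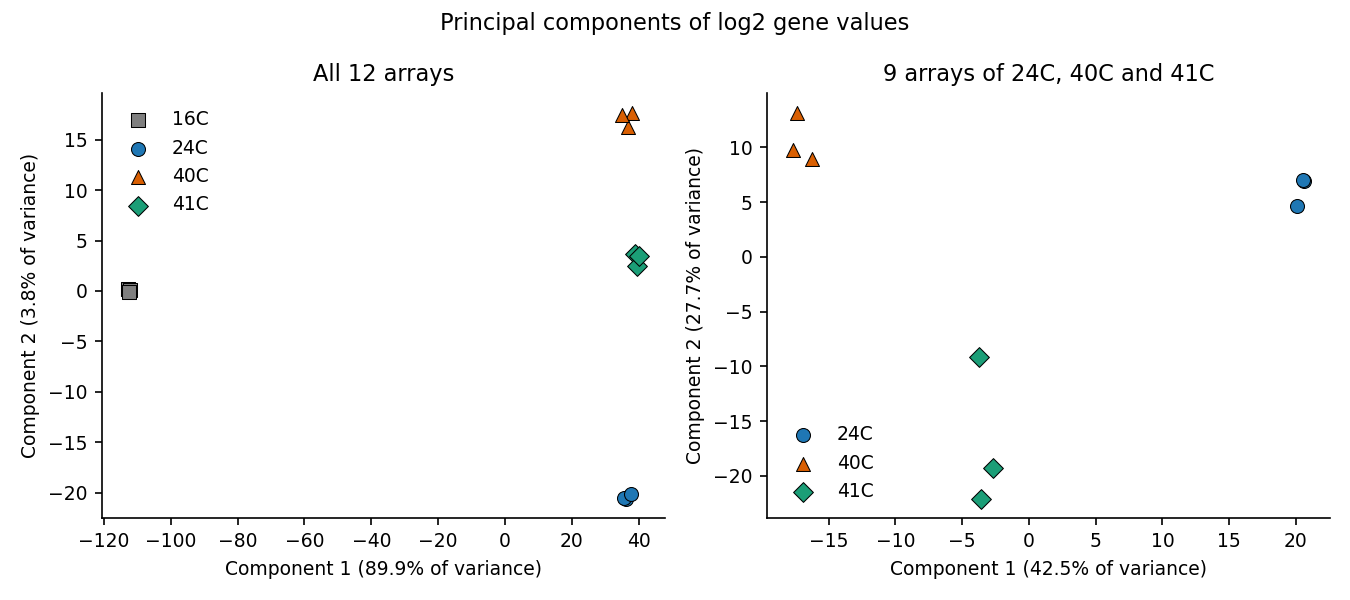
Principal components of the log2 values, with all 12 arrays on the left and the 9 arrays of 24C, 40C and 41C on the right; each point is an array, axes are component scores, and colour and shape give the group. The 16C arrays lie apart on component 1 (89.9% of the variance), and among the 9 arrays components 1 and 2 carry 42.5% and 27.7%.

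Melanocyte genes were far higher in 24C than in 16C and skeletal muscle genes far lower. The melanosome proteins Mlana and Pmel were 869-fold and 232-fold higher, with Mlana at 13.73 in 24C against 3.97 ± 0.11 in 16C (adjusted p = 9.4e-19) and Pmel at 13.75 ± 0.02 against 5.89 ± 0.23 (7.09e-17). The melanin synthesis enzymes Dct and Tyrp1 were 596-fold and 375-fold higher, and the vesicle protein Syt4, the gap junction gene Gjb2 and the chondroitin synthase Chsy3 were 381-fold, 247-fold and 161-fold higher. Dct in 24C, at 14.14 ± 0.02, lay near the highest values of those arrays (14.21 to 14.23), which may limit its fold. Embryonic myosin heavy chain Myh3 was 685-fold lower, at 3.74 ± 0.19 against 13.16 ± 0.25 (adjusted p = 2.98e-16). The secreted protein C1qtnf3 was 660-fold lower, the stretch-responsive Ankrd1 486-fold, the myosin light chain Myl4 445-fold, the myogenic transcription factor Myog 442-fold, the troponin Tnnt3 398-fold and Asb5 391-fold. In all, 2749 of 18194 genes were called, 1277 higher and 1472 lower, and 9813 passed the adjusted p alone. The balance moved with processing, to 40.3% higher with cyclic loess and 52.5% with only the brighter genes.

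The gene lists showed the same contrast between 24C and 16C. Of 21 pigmentation genes 19 rose and none fell (median 6.22, adjusted p = 4.39e-17), including the lineage regulators Mitf (46.3-fold) and Sox10 (56.7-fold). Of 25 collagen and matrix genes 19 fell and 2 rose (median -1.90, adjusted p = 1.33e-08), led by Col3a1 at 352-fold and Col5a2 at 300-fold, and of 21 mesenchymal genes 16 fell and 3 rose (median -1.29, adjusted p = 4.9e-06), with the smooth muscle actin Acta2 159-fold lower. TGF-beta targets (18 of 22 fell, 2 rose, adjusted p = 3.32e-05, Id1 42.7-fold lower), NOTCH pathway genes (11 of 17 fell, adjusted p = 0.000207, Notch3 20.6-fold lower), YAP targets (12 of 19 fell, 5 rose, adjusted p = 0.00717), angiogenic factors and their antagonists (13 of 23 fell, 5 rose, adjusted p = 0.00954, Sema3a 38.5-fold lower), MHC class I genes (8 of 14 fell, adjusted p = 0.00393, Tap2 4.97-fold lower) and neural-crest-like invasive-state genes (11 of 18 fell, 1 rose, adjusted p = 0.00041, Axl 28.1-fold lower) were lower as lists. Lysosome genes (22 of 26 rose, 3 fell, median 0.93, adjusted p = 1.03e-06, Gla 4.11-fold), mitosis genes (22 of 29 rose, median 0.60, adjusted p = 2.88e-06, Bub1 2.34-fold) and hypoxia genes (16 of 21 rose, 5 fell, adjusted p = 0.000779) were higher. Within the hypoxia list the oxidoreductase Ero1a was 14.4-fold higher, while Lox and Egln3 were 28.3-fold and 16.1-fold lower. Adjusted over the list alone, 20 collagen and matrix genes, 19 TGF-beta targets and 14 angiogenic factors fell and 23 mitosis genes rose, and the other counts of these lists were the same as over all genes.

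Another 8 lists passed in 24C versus 16C with the preset correlation and not with an estimated one. Since 9813 of 18194 genes passed the adjusted p in this comparison, the number of members that moved does not by itself set a list apart. ATF4 stress-response genes rose in 21 of 27 members and fell in 3, with Ddit3 10.8-fold and Trib3 7.17-fold higher (adjusted p = 0.0514 with an estimated correlation). Glycolysis genes rose in 14 of 18 and fell in 1, led by Pfkp at 7.15-fold (adjusted p = 0.0572 with an estimated correlation), and DNA replication genes rose in 20 of 29 and fell in 3, led by Mcm2 at 2.68-fold (adjusted p = 0.151 with an estimated correlation). Fibroblast markers fell in 14 of 19 and rose in 1, with Loxl1 177-fold lower (adjusted p = 0.0586 with an estimated correlation), and heat shock genes fell in 11 of 19 and rose in 3, with Hspb1 52.7-fold lower (adjusted p = 0.161 with an estimated correlation). IGF signalling genes fell in 9 of 17 and rose in 4, with Igf2 47.5-fold lower (adjusted p = 0.0586 with an estimated correlation). Cytokines fell in 12 of 25 and rose in 2, with Csf1 7.82-fold lower (adjusted p = 0.0586 with an estimated correlation), and p53 targets fell in 10 of 21 and rose in 4, with Eda2r 39.7-fold lower (adjusted p = 0.146 with an estimated correlation). For 3 of these lists the counts grew when adjusted over the list alone, to 21 DNA replication genes risen and 10 IGF genes and 11 p53 targets fallen, and the other counts of these lists were the same as over all genes. With only brighter genes, camera also lost the fibroblast, IGF, cytokine and p53 lists (adjusted p = 0.0668, 0.138, 0.119 and 0.18). With cyclic loess it lost the cytokines (adjusted p = 0.0609).

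Markers of other cells moved with the same contrast. On a list of 37 skeletal muscle genes written after the leading genes had been seen, 35 fell in 24C, in 40C and in 41C, with medians of -6.97, -7.06 and -6.99 against 16C. Myod1, which directs muscle fate and was chosen after its values were seen, was at 11.74 ± 0.06 in 16C and 4.76 ± 0.19 in 24C. Xist, the RNA that coats the inactive X chromosome, was at 10.02 ± 0.08 in 16C and at 5.46 ± 0.14, 5.49 ± 0.10 and 5.52 ± 0.15 in 24C, 40C and 41C. The Y-linked genes Eif2s3y, Kdm5d, Uty, Usp9y and Zfy2 had group means of 2.90 to 4.48, below the table's median, and Sry of 5.94 to 6.01. None of the 6 passed in any comparison by limma, with lowest adjusted p of 0.184, 0.22 and 0.509 in 24C, 40C and 41C against 16C. Of the fixed marker lists of other cell types, those of macrophages, lymphocytes, endothelium, keratinocytes and Schwann cells passed in none of the 6 comparisons, with lowest adjusted p of 0.204, 0.339, 0.383, 0.253 and 0.0865. Fibroblast markers passed in each comparison with 16C, moving with the collagen and mesenchymal genes. Beside the fall in 24C given above, 12 of 19 fell and 1 rose in 40C (13 and 1 adjusted over the list alone, median -0.70, adjusted p = 0.000332, adjusted p = 0.0868 with an estimated correlation). In 41C 13 of 19 fell and 1 rose (13 and 1 adjusted over the list alone, median -0.76, adjusted p = 0.000314, adjusted p = 0.0699 with an estimated correlation). With only brighter genes the fibroblast list did not pass by camera in 40C or 41C against 16C either (adjusted p = 0.0777 and 0.0844).

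**Figure D2:**
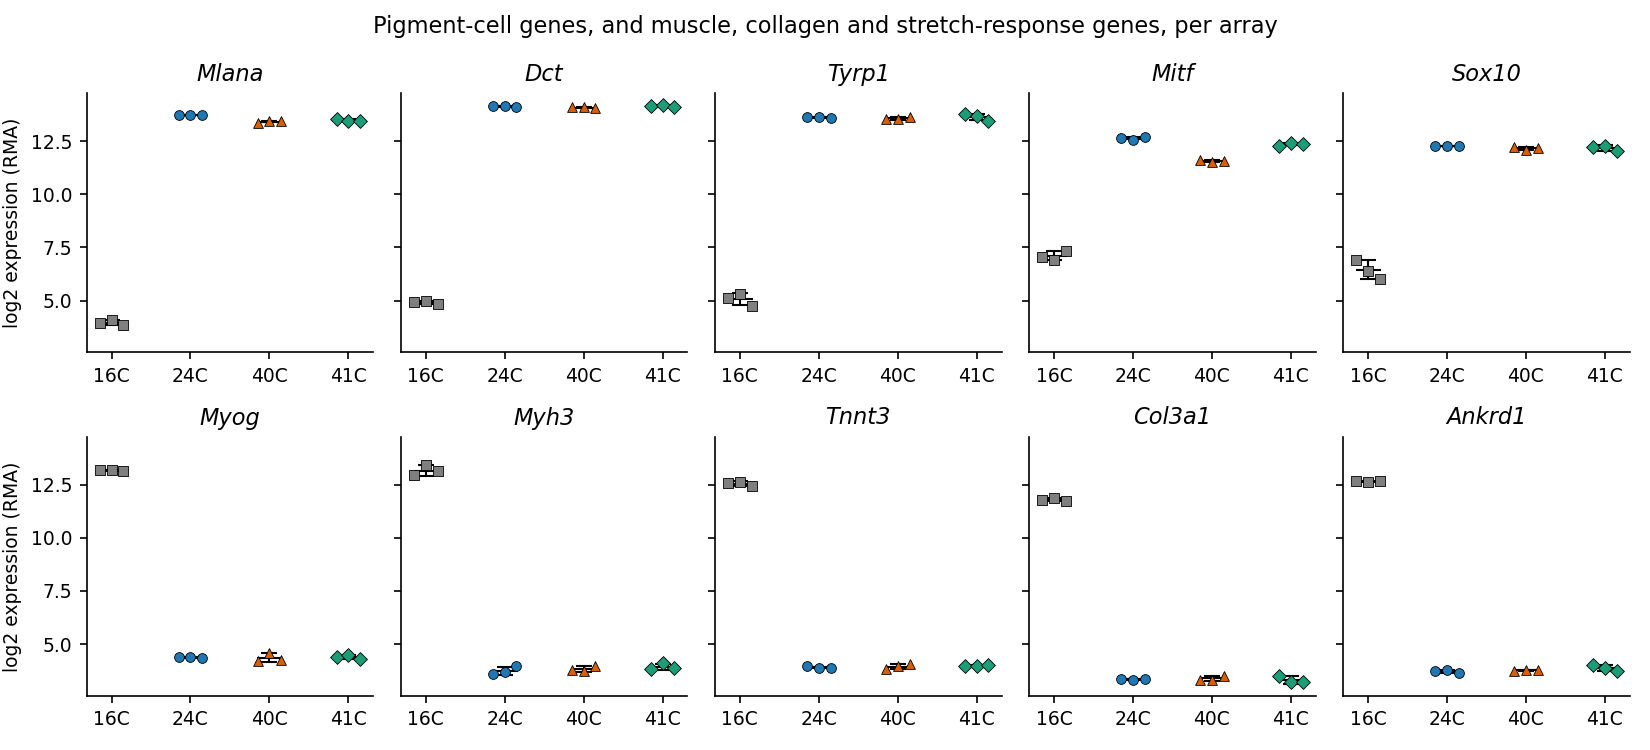
Log2 expression (RMA) of 5 pigment-cell genes in the upper panels and of 5 muscle, collagen and stretch-response genes in the lower panels; each point is an array, horizontal bars are the mean and SD of 3 arrays, and the x axis gives the group. Mlana lies at 13.41 to 13.73 in 24C, 40C and 41C and at 3.97 in 16C, and Myog lies at 4.36 to 4.39 and at 13.17.

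The comparison of 40C with 16C gave a similar list of leading genes. Mlana was 693-fold higher (13.41 ± 0.03 against 3.97 ± 0.11, adjusted p = 1.47e-18), Dct 570-fold, Tyrp1 363-fold, Syt4 270-fold, Pmel 207-fold, the neuronal adhesion molecule Nrcam 197-fold and Chsy3 161-fold. C1qtnf3 was 644-fold lower, Myh3 643-fold, Ankrd1 472-fold, Myl4 466-fold, Myog 451-fold, the calcium-binding protein S100a6 406-fold and Tnnt3 386-fold. Called genes numbered 2786, with 1395 higher and 1391 lower, and 9803 passed the adjusted p alone. The muscle list and Xist differed as given above.

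Of the fixed lists, pigmentation genes rose in 40C versus 16C in 19 of 21 members and fell in 1 (median 5.86, adjusted p = 3.33e-15). Lysosome genes rose in 22 of 26 and fell in 1 (adjusted p = 2.07e-07, Ctsa 3.82-fold). Collagen and matrix genes fell in 18 of 25 and rose in 2 (adjusted p = 1.03e-08, Col3a1 342-fold), mesenchymal genes fell in 16 of 21 and rose in 3 (adjusted p = 9.09e-06, Acta2 165-fold), TGF-beta targets fell in 16 of 22 and rose in 1 (adjusted p = 3.38e-05, Id1 53.1-fold), and MHC class I genes fell in 13 of 14 (adjusted p = 5.6e-05, Psmb8 4.42-fold). There were 20 collagen, 17 mesenchymal and 17 TGF-beta genes that fell when adjusted over the list alone, and the remaining counts were the same. These 6 lists were the ones that also passed with an estimated correlation. ATF4 response genes rose in 21 of 27 and fell in 3, with Ddit3 20.2-fold higher (adjusted p = 0.0518 with an estimated correlation). NRF2 antioxidant genes rose in 11 of 18 and fell in 4 (adjusted p = 0.0988 with an estimated correlation), with Tkt of the pentose phosphate pathway 4.49-fold higher and the glutathione transferase Gsta4 16.7-fold lower. In these lists 22 ATF4 genes and 11 NRF2 genes rose when adjusted over the list alone. Another 10 lists passed only with the preset correlation.

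In 41C versus 16C the same pigment and muscle genes led. Mlana was 733-fold higher (13.49 ± 0.06 against 3.97 ± 0.11, adjusted p = 1.32e-18), Dct 595-fold, Syt4 399-fold, Tyrp1 380-fold, Pmel 244-fold, Nrcam 229-fold and Chsy3 182-fold. C1qtnf3 was 654-fold lower, Myh3 597-fold, Ankrd1 444-fold, Myog 441-fold, Myl4 435-fold, S100a6 415-fold and Asb5 409-fold. Called genes numbered 2903, with 1390 higher and 1513 lower, and 10051 passed the adjusted p alone.

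Cholesterol synthesis genes fell in 41C versus 16C in 16 of 20 members and rose in 1 (median -0.51, adjusted p = 0.000141), with Hsd17b7 3.46-fold and Idi1 3.18-fold lower. ATF4 response genes rose in 24 of 27 and fell in 2 (median 0.77, adjusted p = 9.39e-08), with Ddit3 26.5-fold and Trib3 13.3-fold higher. Hypoxia genes rose in 16 of 21 and fell in 4 (median 1.40, adjusted p = 3.1e-05, Ero1a 20.4-fold higher, Lox 30.2-fold lower), and glycolysis genes rose in 15 of 18 and fell in 1 (adjusted p = 8.18e-06, Pfkp 10.1-fold). Pigmentation genes rose in 19 of 21 (median 6.01, adjusted p = 2.36e-16), lysosome genes in 22 of 26 with 1 fall (adjusted p = 9.82e-08) and mitosis genes in 24 of 29 (adjusted p = 3.12e-07, Hmmr 2.54-fold). Collagen and matrix genes fell in 19 of 25 and rose in 2 (adjusted p = 2.54e-08), mesenchymal genes fell in 16 of 21 and rose in 3 (adjusted p = 6.76e-06, S100a4 105-fold), TGF-beta targets fell in 16 of 22 and rose in 2 (adjusted p = 0.000173), MHC class I genes fell in 11 of 14 and rose in 1 (adjusted p = 0.000118), NOTCH pathway genes fell in 11 of 17 and rose in 1 (adjusted p = 0.00033) and neural-crest-like invasive-state genes fell in 13 of 18 and rose in 1 (adjusted p = 0.000394). When adjusted over the list alone, 20 collagen and 17 mesenchymal genes fell, and the other counts were the same. These 13 lists passed with an estimated correlation too. A further 12 did not, among them heat shock genes, of which 15 of 19 fell and 3 rose (15 and 3 adjusted over the list alone), with Hspb1 106-fold lower (adjusted p = 0.0545 with an estimated correlation).

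The comparisons with 16C shared most of their calls. In 24C, 40C and 41C, 2232 genes were called in the same direction against 16C, 1004 higher and 1228 lower, and none in opposite directions. Mlana, Dct, Tyrp1 and Syt4 led the rises and C1qtnf3, Myh3, Ankrd1 and Myog the falls. The limma fit gave 0 genes in all 3 lists in the mean of 100 simulations of unchanged groups against shared simulated controls. These simulations draw noise independently for each gene, so 0 calls of this size follow from the setting and add no support. Independent lists of the observed lengths would share 7.48 higher and 9.36 lower genes. Across genes, the changes of 24C and 40C correlated at 0.969, of 24C and 41C at 0.976 and of 40C and 41C at 0.979, against 0.501, 0.5 and 0.5 in the simulations. The covariances were 1.20, 1.23 and 1.23, against 0.00442, 0.00441 and 0.00440. The simulations hold shared control arrays with the spread pooled over groups and genes. Whatever sets all 16C arrays apart, including what goes with their tag, enters the 3 comparisons alike and is not in the simulations. Separate controls for each comparison were not possible, since 3 arrays cannot be split into parts of at least 2 arrays each.

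Among the groups that share a tag, 24C differed from 40C most in Pycard and Tmem98. Pycard, the adaptor of the inflammasome, was at 8.13 ± 0.15 in 24C and 4.18 ± 0.21 in 40C (15.4-fold, adjusted p = 4.79e-10), and the membrane protein Tmem98 at 8.42 ± 0.09 and 4.68 ± 0.21 (13.4-fold, adjusted p = 1.29e-10), while in 16C Pycard was at 4.56 ± 0.20 and Tmem98 at 10.19 ± 0.07. The heparan sulfate sulfotransferase Hs3st1 and the membrane protein Ano3 were 7.02-fold and 6.57-fold higher in 24C. The circadian transcription factor Dbp was 7.07-fold lower in 24C (7.26 ± 0.20 against 10.09 ± 0.05, adjusted p = 4.79e-10), myelin basic protein Mbp 6.83-fold, the retinal reductase Dhrs3 5.54-fold and the iron exporter Slc40a1 5.36-fold. Called genes numbered 212, with 72 higher and 140 lower in 24C, and 4062 passed the adjusted p alone.

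Melanocyte genes were higher in 24C than in 40C, with 10 of 21 risen and 1 fallen (median 0.29, adjusted p = 7.03e-05), led by the receptors Met (2.44-fold) and Mc1r (2.15-fold) and by Mitf (2.11-fold, 12.64 ± 0.06 against 11.56 ± 0.04). NRF2 antioxidant genes were lower in 24C, with 11 of 18 fallen (median -0.31, adjusted p = 4.96e-06, Osgin1 2.37-fold), as were YAP targets with 9 of 19 fallen (adjusted p = 0.000564, Axl 2.54-fold) and interferon-stimulated genes with 13 of 29 fallen and 2 risen (adjusted p = 0.00318, Ifit3 2.27-fold). Mitosis genes were higher in 24C with 9 of 29 risen (median 0.14, adjusted p = 7.03e-05), and hypoxia genes with 11 of 21 risen and 3 fallen (adjusted p = 0.00318). In that list Adm was 2.52-fold higher and Egln3 2.06-fold lower. Adjusted over the list alone, 12 NRF2 genes fell and the other counts of these 6 lists were the same.

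A further 8 lists passed in 24C versus 40C with the preset correlation only. DNA replication genes rose in 16 of 29 (19 adjusted over the list alone), with Tyms 2.24-fold higher (adjusted p = 0.101 with an estimated correlation). FOXO targets fell in 11 of 20 and rose in 1 (14 and 1 adjusted over the list alone), with Gadd45a 2.84-fold lower (adjusted p = 0.0933 with an estimated correlation). ATF6 and XBP1 unfolded-protein-response genes rose in 12 of 25 and fell in 2 (14 and 3 adjusted over the list alone), with Sdf2l1 2.16-fold higher (adjusted p = 0.133 with an estimated correlation). Integrins and laminins fell in 9 of 24 and rose in 1 (10 and 1 adjusted over the list alone), with Itgb5 3.31-fold lower (adjusted p = 0.151 with an estimated correlation).

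Between 24C and 41C, Pycard and Tmem98 again differed most, being 16.3-fold and 14.7-fold higher in 24C (8.13 ± 0.15 against 4.10 ± 0.12, adjusted p = 4.01e-10, and 8.42 ± 0.09 against 4.54 ± 0.13, adjusted p = 8.21e-11). Car8 and Hacd4 were 6.6-fold and 5.42-fold higher. Mbp was 4.16-fold lower in 24C (adjusted p = 1.2e-06), the tetraspanin Cd82, known as a metastasis suppressor, 3.63-fold, Angptl6 3.57-fold and Dbp 3.09-fold. The 1 other bright probe set of Cd82 went the other way in this comparison. Called genes numbered 102, with 42 higher and 60 lower in 24C, and 3598 passed the adjusted p alone. With the mean of all probe sets of a gene, 67 were called.

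Cholesterol synthesis and DNA replication genes were higher in 24C than in 41C and hypoxia genes lower. Cholesterol genes were higher in 17 of 20 members and lower in 1 (median 0.61, adjusted p = 2.3e-16), led by Dhcr7 at 2.22-fold (10.02 ± 0.02 against 8.87 ± 0.12) and Idi1 at 2.16-fold. DNA replication genes rose in 24 of 29 (median 0.57, adjusted p = 5.94e-22), led by Cdc6 at 2.05-fold. Hypoxia genes fell in 15 of 21 (median -0.45, adjusted p = 2.95e-10), led by Egln3 at 2.25-fold and Ndrg1 at 1.81-fold. ATF4 response genes fell in 13 of 27 and rose in 1 (adjusted p = 1.4e-08), led by the phosphatase subunit Ppp1r15a at 2.94-fold, the stress protein Nupr1 at 2.54-fold and Ddit3 at 2.46-fold. Ribosome biogenesis genes rose in 22 of 26 and fell in 1 (median 0.41, adjusted p = 1.83e-12), heat shock genes rose in 11 of 19 and fell in 1 (adjusted p = 8.86e-08, Hsph1 2.3-fold), interferon-stimulated genes rose in 11 of 29 and fell in 1 (adjusted p = 0.000289, Trim30a 2.32-fold), and MHC class I genes rose in 6 of 14 and fell in 1 (adjusted p = 0.00215, Erap1 1.63-fold). Adjusted over the list alone, 19 cholesterol, 27 DNA replication, 23 ribosome biogenesis, 12 heat shock, 12 interferon and 8 MHC genes rose, 15 ATF4 genes fell, and the hypoxia count was the same. These 8 lists passed with an estimated correlation too, and 5 more did not.

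The unfolded-protein-response list was one of those 5, with 9 of 25 members higher in 24C than in 41C and 4 lower (11 and 4 adjusted over the list alone, adjusted p = 0.345 with an estimated correlation). Without replicate 1 of 41C its adjusted p was 0.186. Pdia4 on that list was at 8.69 ± 0.06 in 24C and 9.70 ± 0.90 in 41C.

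In 40C versus 41C, Hs3st1 and Ano3 were lower in 40C by 10.2-fold (6.36 ± 0.11 against 9.71 ± 0.09, adjusted p = 1.34e-09) and 5.78-fold (4.77 ± 0.55 against 7.30 ± 0.27, adjusted p = 7.08e-06), as were the ion exchanger Slc24a4 by 3.57-fold and Selenbp1 by 3.4-fold. The succinate receptor Sucnr1 was 3.78-fold higher in 40C (6.37 ± 0.32 against 4.45 ± 0.18, adjusted p = 9.87e-07), Cpt1a, which admits fatty acids to mitochondria for oxidation, 3.63-fold, the chemokine-scavenging receptor Ackr4 3.37-fold and Lrrc75b 3.29-fold. Called genes numbered 96, with 48 higher and 48 lower in 40C, and 2846 passed the adjusted p alone.

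Hypoxia genes were lower in 40C than in 41C in 18 of 21 members and higher in none (median -0.57, adjusted p = 1.02e-20), with Ankrd37 2.7-fold, the glucose transporter Slc2a1 2.18-fold and Adm 2.14-fold lower. Cholesterol synthesis genes were higher in 40C in 17 of 20 (median 0.78, adjusted p = 1.65e-20), with Idi1 2.49-fold, Hmgcs1 2.23-fold and Dhcr7 2.2-fold, and fatty acid synthesis genes in 13 of 17 (median 0.40, adjusted p = 1.68e-09), with the synthase Fasn 2.56-fold and the elongase Elovl6 2.38-fold. Interferon-stimulated genes rose in 18 of 29 (median 0.36, adjusted p = 3.04e-12, Ifit3 2.47-fold) and NRF2 antioxidant genes in 12 of 18 (median 0.51, adjusted p = 2.08e-10, Srxn1 2.49-fold). Glycolysis genes fell in 9 of 18 (adjusted p = 7.74e-10, Hk2 2.07-fold), mitosis genes in 14 of 29 (adjusted p = 5.37e-10, Ndc80 1.43-fold), ATF4 response genes in 11 of 27 with 1 rise (adjusted p = 2.9e-08, Ppp1r15a 2.08-fold), immediate early genes in 10 of 25 (adjusted p = 0.000185, Nr4a3 2.46-fold) and pigmentation genes in 6 of 21 with 1 rise (adjusted p = 1.38e-05, Trpm1 1.92-fold). These 10 lists passed with an estimated correlation too. Adjusted over the list alone, 18 cholesterol, 19 interferon and 13 NRF2 genes rose, 13 glycolysis, 19 mitosis, 13 ATF4 and 11 immediate early genes fell, with 1 NRF2 gene fallen and 3 immediate early genes risen, and the other counts were the same. DNA replication genes rose in 14 of 29 (23 risen and 1 fallen adjusted over the list alone, adjusted p = 0.0533 with an estimated correlation), and heat shock genes in 9 of 19 (11 adjusted over the list alone, adjusted p = 0.0544 with an estimated correlation).

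**Figure D3:**
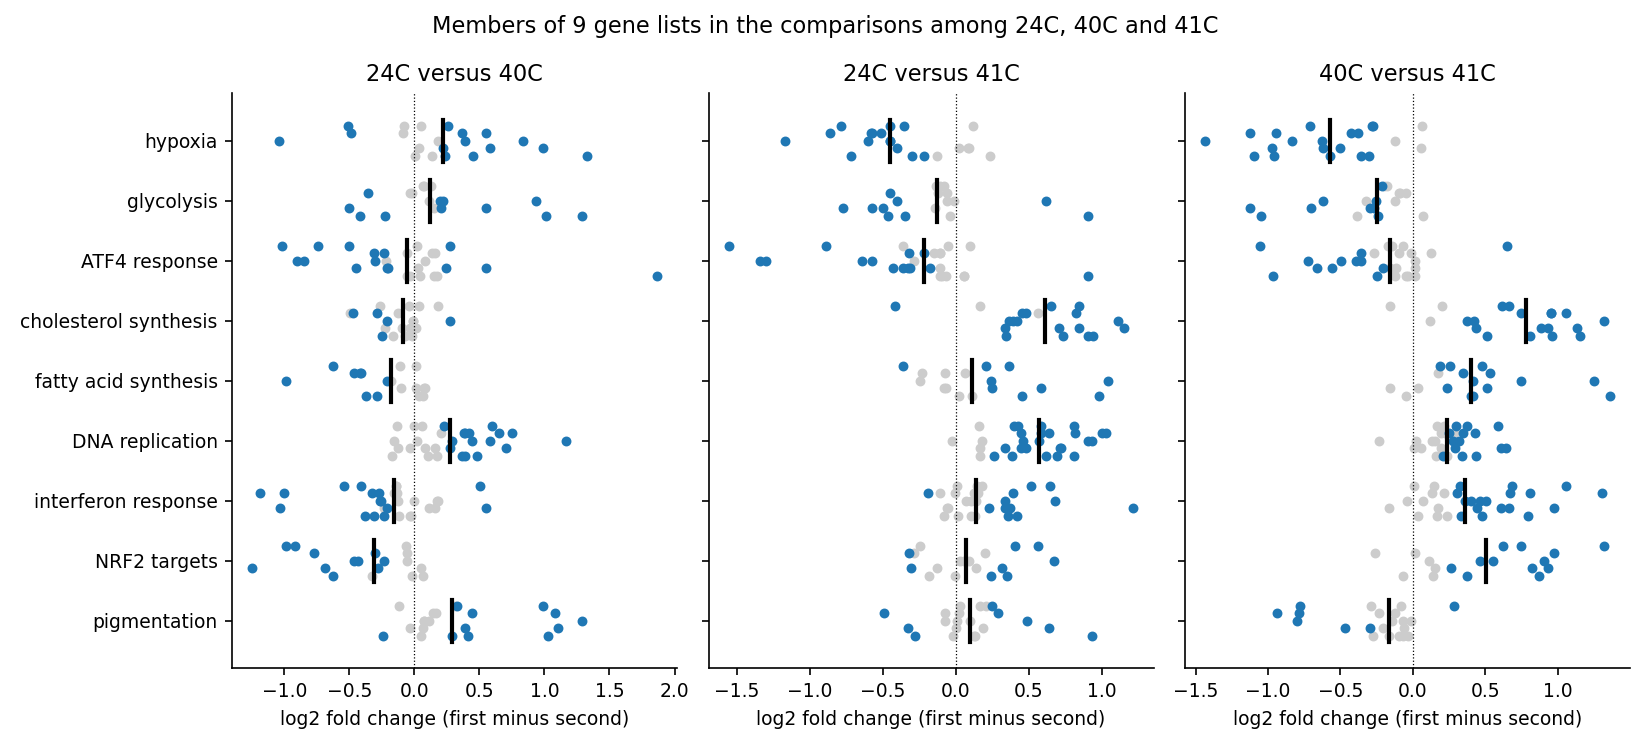
Log2 fold change (first group minus second) of each member of 9 gene lists in the 3 comparisons among 24C, 40C and 41C; each point is a gene, blue with an adjusted p under 0.05 and grey otherwise, and black bars are list medians. Hypoxia genes have medians of -0.45 and -0.57 against 41C, and cholesterol synthesis genes medians of 0.61 and 0.78.

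Of 24C, 40C and 41C, each was set apart from the 3 other groups by few called genes. With no minimum size of change, 999, 707 and 658 genes set them apart. For 24C the called genes numbered 23, with 9 higher and 14 lower. Pycard (8.13 ± 0.15 against 4.56 ± 0.20 in 16C), Car8, the kinase Stk26 and Slc44a3 led the higher ones, and Cd82, Dhrs3, the protease Prss23 and Tmem141 the lower ones. As given above, the other bright probe set of Cd82 went the other way against 41C. Prss23 was at 6.71 ± 0.19 in 24C and at 10.08 ± 0.07, 9.06 ± 0.17 and 8.06 ± 0.16 in 16C, 40C and 41C. For 40C there were 20 genes, 15 higher and 5 lower, with Sucnr1, Slc25a34, Lrrc75b and the complement protease C1s1 higher and caveolin Cav1, Emp1, the retrieval receptor Kdelr3 and adrenomedullin Adm lower. Cav1 was at 6.84 ± 0.16 in 40C and at 10.81 ± 0.07, 8.48 ± 0.04 and 8.20 ± 0.07 in 16C, 24C and 41C. For 41C there were 7, with Retreg3, Slc24a4 and Ppp1r15a among the 4 higher and Idi1, Elovl6 and Ackr4 the 3 lower. Idi1 was at 8.43 ± 0.10 in 41C and at 10.10 ± 0.04, 9.53 ± 0.08 and 9.74 ± 0.04 in 16C, 24C and 40C, and Retreg3 was at 8.33, 9.85 and 9.29 on the 3 arrays of 41C. With only the brighter genes 17 set 24C apart, 17.6% of them higher, but that filter drops genes high in 24C alone more readily. Without the 16C arrays, an alternative chosen after seeing the data, 62 and 51 genes set 24C and 40C apart from the 2 remaining groups, and with the mean of all probe sets of a gene 3 genes set 41C apart.

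**Figure D4:**
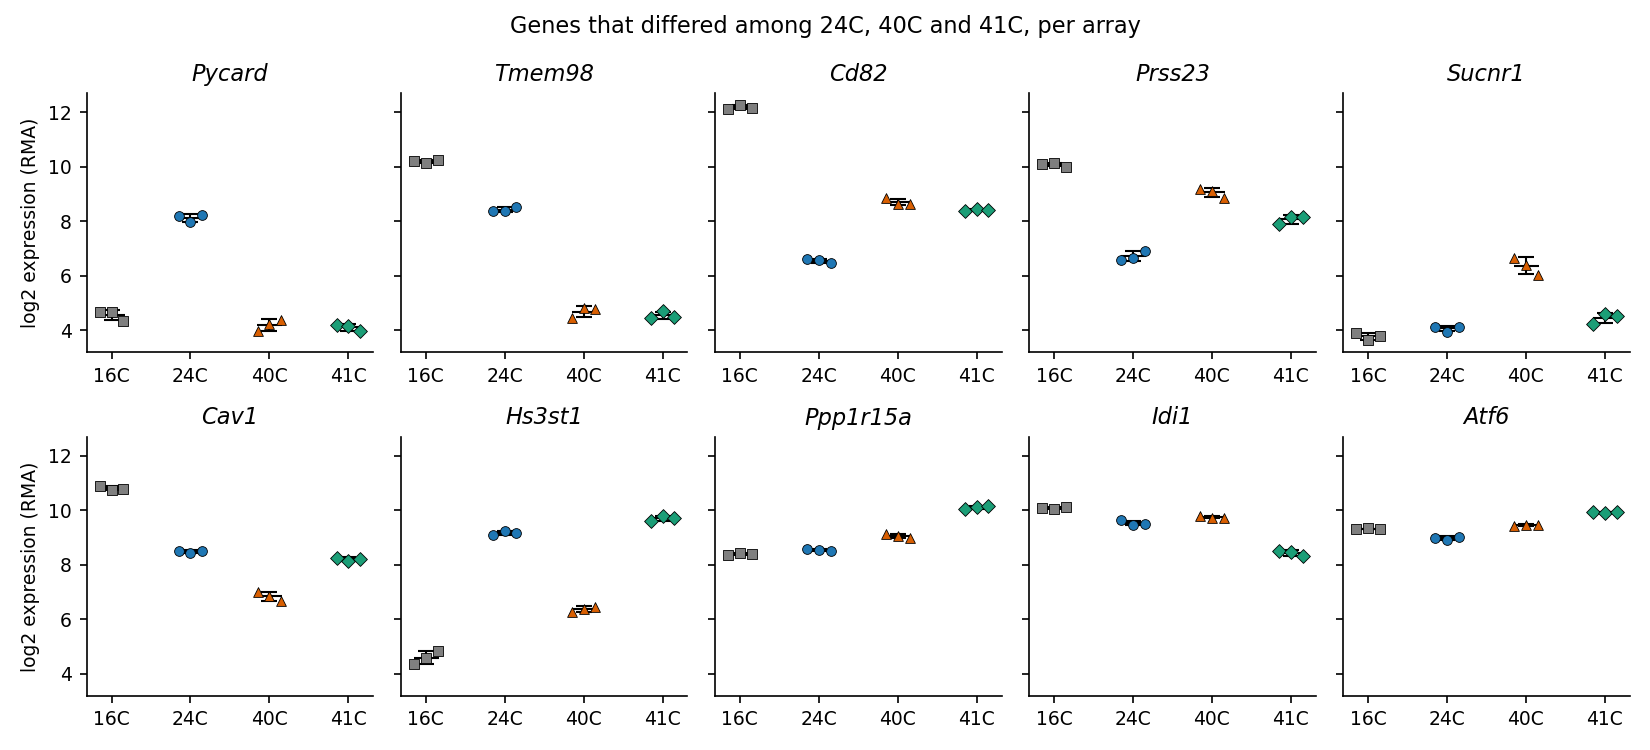
Log2 expression (RMA) of 10 genes that differed among 24C, 40C and 41C; each point is an array, horizontal bars are the mean and SD of 3 arrays, and the x axis gives the group. Pycard lies at 8.13 in 24C and at 4.10 to 4.56 in the other groups, and Ppp1r15a at 10.10 in 41C and at 8.39 to 9.05 in the others.

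Of the genes of interest fixed beforehand, the growth factor receptor Igf1r was lower than in 16C (8.62 ± 0.08) by 3.39-fold in 24C, 2.45-fold in 40C and 3.1-fold in 41C, and the kinase Braf was higher by 2.25-fold, 2.83-fold and 3.06-fold, all 6 differences being called. Mitf was at 7.11 ± 0.22 in 16C and 21.9-fold and 37.8-fold higher in 40C and 41C, and Sox10 52.4-fold and 52.9-fold. The nucleotidase Entpd5, which acts in glycoprotein folding in the endoplasmic reticulum, was at 8.83 ± 0.05 in 41C and at 8.20 ± 0.06, 8.25 ± 0.08 and 8.17 ± 0.15 in 16C, 24C and 40C (adjusted p = 6.22e-06, 0.000154 and 6.61e-05), and its 4 other bright probe sets differed the same way in each. The stress sensor Atf6 was also highest in 41C, at 9.92 ± 0.03 against 9.45 ± 0.03 in 40C, 9.31 ± 0.01 in 16C and 8.98 ± 0.06 in 24C (adjusted p = 9.06e-05, 4.04e-07 and 2.03e-07), though 1 of its 2 other bright probe sets went the other way against 16C. The chaperone Hspa5 was at 12.64 ± 0.06, 12.51 ± 0.03, 12.17 ± 0.08 and 12.07 ± 0.06 in 16C, 24C, 40C and 41C. The RNA-binding protein Cirbp was called lower in each of 24C, 40C and 41C than in 16C, by 3.22-fold, 3.5-fold and 2.65-fold. Nras was at 9.51 ± 0.13, 10.17, 9.66 ± 0.09 and 9.95 ± 0.04 in the same order, with another of its probe sets going the other way against 16C, and Cdkn2a at 3.67 to 3.97, near background. As a list, PI3K-AKT-mTOR pathway components passed in 40C versus 41C alone of the 6 comparisons, with 4 of 22 members lower in 40C and none higher (7 adjusted over the list alone, adjusted p = 0.00948, adjusted p = 0.207 with an estimated correlation), and metastasis suppressor genes passed in none, with a lowest adjusted p of 0.167.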

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

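The fit without the 16C arrays was chosen after seeing the data, and the other alternatives were planned. Every count of called genes stayed within 1.5 times its value, including the 84 counts with an array left out, except as follows. With no minimum size, 9813, 9803 and 10051 genes differed from 16C in 24C, 40C and 41C, 4062 in 24C versus 40C, 3598 in 24C versus 41C and 2846 in 40C versus 41C, 7588 were shared by the 3 comparisons with 16C, and 999, 707 and 658 set 24C, 40C and 41C apart, since that alternative drops one of the criteria. With the mean of all probe sets of a gene, 67 genes were called in 24C versus 41C and 3 set 41C apart, and the cause was not tested. Without the 16C arrays, 62 and 51 genes set 24C and 40C apart, since fewer groups must be exceeded. With every probe set on its own, another probe set of the gene turned the direction in 40C versus 16C of Entpd5 (0.22, adjusted p = 0.0257), Atf6 (-0.40, adjusted p = 0.000232) and Nras (-0.62, adjusted p = 4.17e-05). That alternative takes the probe set with the lowest p of each gene, so these values are selected extremes. In the main fit the means of these genes in 40C and 16C lay close together, as given above. With each array left out in turn, 24C versus 16C gave 2732 to 2791 genes, 40C versus 16C 2762 to 2837, 41C versus 16C 2874 to 2949, 24C versus 40C 211 to 222, 24C versus 41C 91 to 128 and 40C versus 41C 92 to 128, the shared genes numbered 2211 to 2253, and those setting 24C, 40C and 41C apart 22 to 26, 19 to 23 and 5 to 10. The share of called genes that were higher than in 16C, at 46.5%, 50.1% and 47.9% in 24C, 40C and 41C, became 40.3%, 44.7% and 42.7% with cyclic loess and 52.5%, 56.3% and 53.9% with only brighter genes, and that of the genes setting 24C apart went from 39.1% to 17.6% (17 genes) with only brighter genes. Of 109 list calls, 55 held with an estimated correlation and 54 did not, 22 were lost with only brighter genes, 8 with cyclic loess, 6 with the mean of all probe sets and 1 with arrays shifted to one median, while 18 of 654 refits with an array left out lost a call. Fry passed 43, 44 and 45 of 46 lists against 16C and so says nothing about stability. The differences of Pdia4 and Mitf between 24C and 41C and of Notch2, Pdpk1 and Nras between 40C and 41C lost their adjusted p under several alternatives. Log2 of linear values was not run, since the values were already log2. Signal over background limits the folds of genes near background, such as the muscle genes in 24C, 40C and 41C.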

Other observations

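Of the tests below, those on pigment-cell genes in 16C, on the muscle list, on other genes of the same level and on other splits of the arrays were chosen only after the result was seen.

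The lists of other muscle and mesenchymal tissues, written after the leading genes were seen, did not move as the skeletal list did. Heart muscle genes had medians of -0.13, -0.19 and -0.08 in 24C, 40C and 41C against 16C, fat genes -0.13, -0.0034 and -0.17, and cartilage or bone genes 0.02, -0.05 and 0.02. Smooth muscle genes lay lower, with medians of -0.98, -0.97 and -0.97 and 7, 7 and 8 of 13 members fallen. In 16C the myoblast fusion genes Mymk and Mymx, chosen after their values were seen, were at 11.73 ± 0.23 and 10.58 ± 0.10 against 4.86 ± 0.10 and 3.25 ± 0.02 in 24C. The acetylcholine receptor subunit Chrna1, chosen likewise, was at 12.52 ± 0.07 against 5.32 ± 0.15. Respiratory chain genes, ribosomal proteins and ERK output genes passed in none of the comparisons with 16C, with ribosomal proteins at adjusted p = 0.142, 0.44 and 0.336.

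Pigment-cell genes lay near background and skeletal muscle genes high on the 16C arrays. The 2 brightest probe sets of a gene shifted together (correlation 0.846 over 5364 genes), which argues against processing that moves probe sets independently as the whole cause. This correlation cannot speak against a labelling or amplification difference, which may move all probe sets of a transcript, as those of the poly-A spikes moved together. The 5 pigment-cell genes stood at a median of 0.276% of their level elsewhere, so 16C held little RNA from cells that express them as the other groups do. Mlana, Dct, Tyrp1 and Pmel had already been seen as leading genes, so this was no independent test. Melanoma cells without pigment genes would not show in it, so a mixture of such cells with muscle cells stays open. Cells of another genetic origin are a candidate explanation on Xist alone, which was higher by 4.53, whereas no Y-linked gene shifted by more than 0.119. A difference in sex is thus not shown, and a change of Xist by itself stays open. The skeletal muscle list lay higher by at least 6.97, but it was written after leading members had been seen and is no independent test. Of its members 4 were among the named genes, and 35 of 37 lay higher in 16C in each comparison. The 16C arrays thus held skeletal muscle transcripts at high levels, while the kind of cells that gave them stays open. Shifts of neighbouring genes correlated at 0.163 in 16C against a highest shuffled value of 0.0295, but also at 0.161, 0.159 and 0.0841 in 24C versus 40C, 24C versus 41C and 40C versus 41C. A laboratory difference that goes with the sample-name tag stays open, at least for smaller shifts, since the hybridisation spikes differed by a median of 0.449 and the poly-A spikes by 1.56. The 3' minus 5' difference of pyruvate carboxylase shifted by 0.836 and that of the transferrin receptor by 0.00741. Pyruvate carboxylase was itself lower outside 16C, where compression may shrink its difference, so its shift cannot tell RNA integrity from level. The differences of b-actin (-0.0672) and Gapdh (-0.0291) lie at the top of the scale and decide nothing. A mislabelled or exchanged sample set was not tested.

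Hypoxia genes were higher and cholesterol synthesis genes lower in 41C than in 24C and 40C. Leaving out any one 41C array left at least 79.4% of the median shift of either list, with adjusted p of at most 1.56e-08, the least being left without replicate 1. Of the other bright probe sets of the genes that moved, 98.7% (75 of 76) went the same way. These values argue against a single array as the source and against misread probe sets. Hybridisation and poly-A spikes varied more within 41C than within the other groups, as given below. A laboratory difference spread over several 41C arrays was not tested. The 2 rescalings left at least 98.1% but moved the median of all genes by at most 0.0137, which alone decides nothing. Scaling is argued against because the 2 lists moved in opposite directions and the 100 other genes nearest in level to each member did not follow. Their medians were between -0.177% and -3.85% of the list's shift, that is, slightly the other way. RMA forces all arrays onto one distribution and so keeps such medians small, which limits the weight of the second point. No biological explanation was tested.

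Pycard and Tmem98 stood near background in 40C and 41C and well above it in 24C, with Tmem98 higher still in 16C. The 10 nearest measured genes did not move with them: their medians were -0.197 and -0.0332 around Pycard and 0.0307 and 0.103 around Tmem98 in 24C versus 40C and versus 41C, which argues against a gain or loss of a block that spans most of those genes. No other explanation was tested.

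Other splits of the arrays were counted for each number of called genes. In each of the 6 comparisons 1 of 10 splits, the real one, gave as many genes, and the highest other gave 0, against real counts of 2749, 2786, 2903, 212, 102 and 96. Every other split mixes the 2 groups, which puts their difference into the spread and lowers the calls. As 10 splits are also too few for a share under 0.05, the splits decide nothing. Of 100 regroupings of the 12 arrays, 1 gave as many shared genes as the real 2232 (highest other 0), 2 as many as the 23 that set 24C apart (highest other 2449), 1 as many as the 20 of 40C (highest other 10) and 3 as many as the 7 of 41C (highest other 2489). The other regroupings that matched a real count were among the 3 that kept the 16C arrays in a single group, which points to the structure of the samples. Without those 3 the highest was 9 for 24C, 10 for 40C and 0 for 41C. In these remaining regroupings the large difference of 16C enters the spread, so their low counts decide little.

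Within 41C, replicate 1 lay apart from replicates 2 and 3 on the second component of the 9 arrays (-9.15 against -19.3 and -22.1). Without replicate 1, 128 genes were called in 24C versus 41C and 128 in 40C versus 41C, against 102 and 96 with all arrays. Hybridisation and poly-A spikes varied more within 41C than within the other groups. The SD of BioB-5 was 1.17 in 41C and 0.39, 0.42 and 0.57 in 16C, 24C and 40C. That of DapX-5 was 1.15 against 0.15, 0.17 and 0.34. A labelling or hybridisation difference among the 41C arrays was not tested.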
